A study of Homo sapiens with 29 samples.

How the data were processed

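The series measured mRNA and cell surface proteins in the same human cells by REAP-seq, in which antibodies carrying DNA barcodes bind to cells before droplet capture, so that antibody tags and mRNA are sequenced from one droplet. Of the 29 samples, 9 came from peripheral blood mononuclear cells (PBMC): 5 mRNA libraries and 4 protein libraries, each condition with 1 library. The other 20 came from cultured naive CD8+ T cells of 3 donors: 10 mRNA libraries and 10 protein libraries, of which 4 of each kind had been stimulated with antibodies to CD3 and CD28 (aCD3+aCD28) and 6 of each kind with an added antibody to CD27 (aCD3+aCD28+aCD27). Groups and donors were taken from the sample labels. Libraries were made on the 10x Genomics Chromium platform, version 1 chemistry, per the labels' protocols, and all CD8+ T cell libraries were labelled with antibodies in blocking buffer.

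The authors deposited whole-number counts per gene or antibody tag and cell barcode, not normalized, with 1 table per library. Per the submitters' processing notes, bcl2fastq 2.17.14, Cell Ranger 1.3, STAR, SAMtools 1.2, Seurat 1.4 and the hg19 genome build were named, with no role or order. How the authors chose the deposited barcodes, and whether a count is a molecule or a read, is not given in the sources used here, and the counts are called UMIs (unique molecular identifiers) after the platform's usual output. The mRNA tables held 32738 gene symbols, without positions. Of these, 99 features on the Y chromosome or at the XIST locus were left out of every table. The tag tables held 47 antibodies in PBMC and 82 in CD8+ T cells, plus a row named Blank that names no antibody. That row held at most 0.000669% of a library's tags and entered no library size or test. Each protein library listed the same barcodes in the same order as its mRNA library.

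Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept: 13660 of 14546 CD8+ T cells and 16963 of 17129 PBMC. Doublets were not removed. The scrublet caller marked 11 of 16963 PBMC (0.0648%), too few for its calls to be of use, so doublets stayed untreated. Libraries of 1 donor and 1 stimulation were not deposits of the same library, since their counts differed by 18.3 to 101 times sampling noise (chi-square over degrees of freedom). They were summed, which left 3 sums per stimulation, and the donor was the unit of replication. P-values of single genes, tags and cell measures reflect the spread between these donors. Those of the main gene list test set a list's genes against the other tested genes. Those of the mRNA and protein responses permute the pairs of antibody and gene. Intervals given for the PBMC libraries are exact 95% intervals that cover counting error only.

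Differences between stimulations were tested on the summed counts with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, trimmed mean of M values scaling, Benjamini-Hochberg adjusted p under 0.05). Genes passed filterByExpr and tags needed at least 10 counts in all. The design held stimulation alone, and an alternative added the donor as a block. The same donors supplied both stimulations, per the labels. The deviations of a donor's 2 sums from their group means were correlated at 0.183, 0.505 and 0.406 over 2378 genes at 50 CPM or more and at 0.608, 0.490 and 0.503 over 60 tags. Between different donors they lay at -0.448 to 0.223 for genes and -0.466 to -0.138 for tags. The donors thus paired the tag samples, and the mRNA samples of donors 2 and 3, while donor 1's mRNA value lay under the highest between donors. DESeq2 1.42.0 (Wald test, for genes without a filter and, added later, with it) and limma 3.58.1 on centred log ratios were alternatives. The 26 gene lists were tested with camera of limma (preset correlation of 0.01), with fry beside it. Single measures were compared with a two-sided exact permutation test over the 3 and 3 donor values, whose smallest possible p is 0.1. The lists were activation receptors, inhibitory receptors, NF-kB pathway and targets, chemokines, cytokines, cytotoxic effectors, naive and central memory genes, effector and memory transcription factors, S phase, G2/M phase, glycolysis, oxidative phosphorylation, cholesterol synthesis, MYC targets and ribosome biogenesis, interferon response, apoptosis regulators, stress and dissociation genes, nuclear and intronic RNA quality, ribosomal proteins, mitochondrially encoded genes, and markers of B cells, monocytes, NK cells, CD4 and regulatory T cells, gamma-delta and MAIT (mucosal-associated invariant T) cells, and platelets with erythroid cells.

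Groups, tests, gene lists, cell markers, the rule for naming genes and most alternatives were chosen before the data were examined. By that rule, genes (at a mean of 50 CPM or more) and tags past the threshold with the same direction in all 3 donors were named, up to 12 genes or 8 tags each way by fold change, with up to 4 examples of each list in order of adjusted p, and always a fixed set that included CD27, CD28, CD3E, CD8A, CD70, IL2RA, TNFRSF9, IL2, IFNG, GZMB, MKI67 and CCR7. IL2 had too few counts to be tested. For single libraries, up to 8 genes or tags in each direction over 2-fold different were named, and of protein and mRNA pairs the 8 highest and 4 lowest with a fixed set of lineage markers.

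PBMC were clustered together on mRNA with scanpy 1.11.5 (10000 counts per cell, 2000 variable genes, 20 principal components, 15 neighbours, Leiden resolution 0.8). A cluster was named X-like where at least 3 of the fixed markers of that class were among its top 10 genes by fold. Shares of cells with a UMI were compared after thinning each cell to 700 UMIs (CD8+ T cells) or 500 UMIs (PBMC). mRNA profiles of single libraries were compared by Pearson's r of log2(CPM + 1) and by genes over 2-fold different among those at 50 CPM (counts scaled to a common total) or more, and tags between blocking conditions where they held at least 30 counts over both libraries.

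The tests were run on simulated counts with the real library sizes. For the mRNA comparison (11261 genes), 0%, 14.1% and 72.3% of genes changed 1.5-fold, 2-fold and 4-fold were called, against 0.0461% of unchanged genes. For the tags (82), 0 of 4, 0 of 4 and 3 of 4 were called at those sizes and 0 of 70 unchanged tags. A glycolysis list raised 1.5-fold was called by camera (adjusted p = 3.04e-18) with 0 of the other lists. The simulated genes were drawn independently of each other. False calls of lists whose genes are correlated in the real data were therefore not checked by it. Alternatives covered scaling, test, filters on genes and cells, equal cell numbers, 1 library per donor and stimulation, each donor left out, thinning depth, clustering settings and pseudocounts. A check of called genes against library depth had been planned for the mRNA comparison and was not run, since no gene was called.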

Results

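REAP-seq libraries of human PBMC and of stimulated naive CD8+ T cells were compared. The PBMC mRNA libraries held 2883 to 4330 cells and 4.17 to 6.31 M UMIs each (M, mega), and the PBMC protein libraries 1.12 to 1.94 M tags. They covered unsorted PBMC without antibodies, with antibodies, and with antibodies in blocking buffer, as well as CD3-enriched and CD11b-enriched PBMC. The CD8+ T cell mRNA libraries held 1.32 to 24.9 M UMIs and the protein libraries 0.620 to 6.65 M tags. Summed per donor and stimulation, mRNA came to 1.85 to 4.21 M UMIs without aCD27 and 16.9 to 37.3 M with it. Tags came to 0.592 to 2.19 M without aCD27 and 7.16 to 9.37 M with it.

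The first question of the CD8+ T cell set was how cell number and depth went with stimulation. Libraries with aCD27 held 1900 ± 134 kept cells (SD, n = 3 donors) and those without it 566.8 ± 46.6, a ratio of 3.35 that was higher in 3 of 3 donors (exact permutation p = 0.1, the smallest possible). Median UMIs per cell were 6872 ± 2579 with aCD27 and 3096 ± 1377 without it (exact permutation p = 0.2), and median genes per cell 1874 ± 545 and 1042 ± 371 (exact permutation p = 0.2). The median mitochondrial share was 4.37% ± 0.551 and 3.37% ± 0.509 (exact permutation p = 0.2). Median tags per cell were 1758 ± 293 and 1294 ± 494 (exact permutation p = 0.3). These 4 medians were higher with aCD27 in 3 of 3 donors, while the exact p compares the donors unpaired. Depth and cell number thus differed between the stimulations in the comparisons below.

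Costimulation through CD27, a receptor of the TNF receptor family on naive T cells, went with a loss of its own antibody tag. The CD27 tag fell by 3.66 on the log2 scale (SE 0.387, adjusted p = 0.000504), from 20240 ± 734 to 1600 ± 577 CPM (SD, n = 3), and was lower in 3 of 3 donors. The tag of CD127, the interleukin-7 receptor alpha chain, fell by 2.36 (SE 0.330, adjusted p = 0.00235), from 380.6 ± 129 to 74.0 ± 13.8 CPM. The tag of CD45RA, the CD45 isoform of naive T cells, fell by 1.55 (SE 0.346, adjusted p = 0.0323), from 34920 ± 5720 to 11930 ± 4660 CPM. CD4 A, one of 2 entries for CD4, the coreceptor of helper T cells, rose by 1.80 (SE 0.361, adjusted p = 0.0218), from 71.7 ± 17.9 to 249 ± 110 CPM. CD11b, an integrin chain of myeloid and some activated lymphoid cells, fell by 1.12 (adjusted p = 0.0377), and the tag of the immunoglobulin lambda light chain fell by 1.56 (adjusted p = 0.0420). Each of the 6 moved the same way in 3 of 3 donors.

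**Figure D1:**
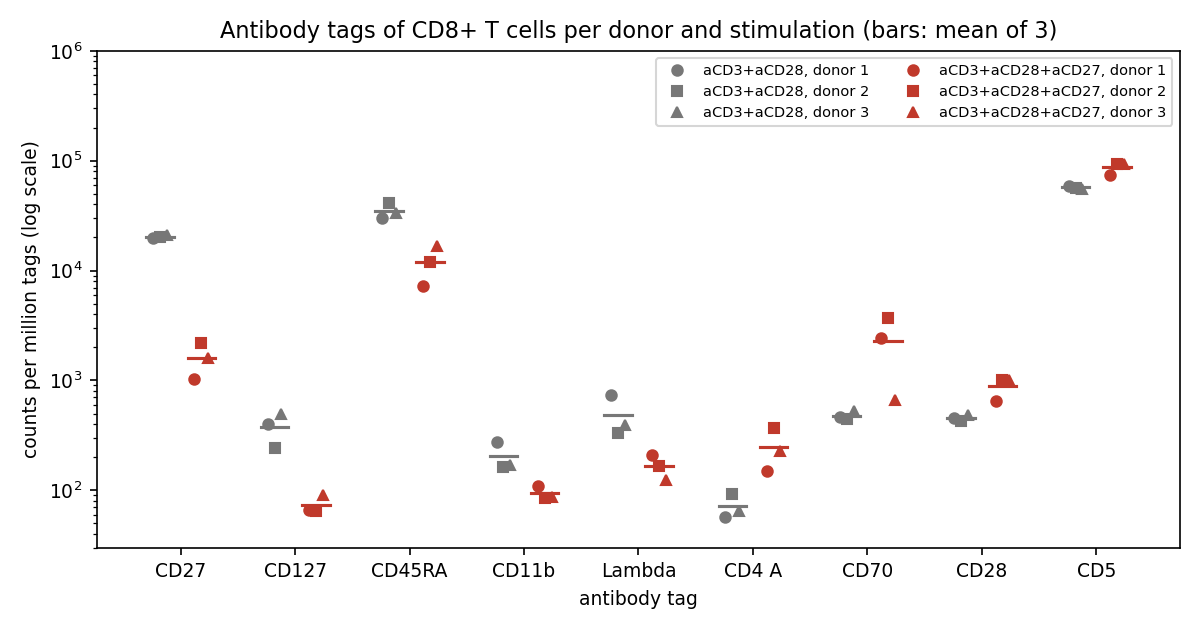
Tag CPM (log scale) for 9 antibodies in CD8+ T cells, with a point per donor (n = 3), a horizontal bar at the mean of 3 donors, grey for aCD3+aCD28 and red for aCD3+aCD28+aCD27. The CD27 tag averaged 20240 CPM without aCD27 and 1600 with it, while CD70, CD28 and CD5 (CD5 chosen after its values were seen) had adjusted p values of 0.0531, 0.0925 and 0.0728.

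These 6 of 82 tags passed edgeR's quasi-likelihood test (1 higher and 5 lower, 24 at an unadjusted p under 0.05). For background, the isotype control tags lay at 32.2 ± 2.79 and 38.5 ± 5.57 (mouse IgG2a), 52.3 ± 7.35 and 46.9 ± 2.07 (mouse IgG2b) 41.6 ± 2.74 and 35.9 ± 2.04 (rat IgG1), and 157 ± 13.7 and 281 ± 137 (mouse IgG1) CPM without and with aCD27. CD4 A thus lay under the mouse IgG1 tag in both stimulations, and CD127 (74.0 CPM), CD11b (94.5 CPM) and lambda (167 CPM) did with aCD27. The 3 CD8 entries did not pass: CD8 A had a log2 fold change of -0.24 (adjusted p = 0.371), CD8 B of -0.29 (adjusted p = 0.504) and CD8a of 0.07 (adjusted p = 0.836). CD3 (0.56, adjusted p = 0.356), CD25 A (0.90, adjusted p = 0.288), CD25 B (-0.09, adjusted p = 0.785) and CD197 (0.36, adjusted p = 0.278) did not pass either. The split of higher against lower calls was 2 and 6 with DESeq2's size factors and 7 and 7 with total counts (5 of the 6 still called). It was 13 and 13 with DESeq2's Wald test, 10 and 7 with limma on centred log ratios, and 8 and 5 with equal cell numbers (4 of the 6 still called). Without donor 1, 2 or 3, 5, 2 and 14 tags were called, 4, 2 and 6 of the 6 among them, and the 2 without donor 2 were CD27 and CD127.

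With the donor as a block, 25 tags passed (11 higher and 14 lower), all 6 above among them. Those added, named after their values were seen, included CD70, the ligand of CD27, at 478.0 ± 41.4 CPM without aCD27 and 2267 ± 1520 CPM with it (log2 fold change 2.25, SE 0.597, without the block), and CD137, a costimulatory receptor of activated T cells, at 1.02 (SE 0.404) with it. CD28 was at 0.94 (SE 0.343), CD155 at 1.28 (SE 0.384), CD366 (TIM-3) at 1.08 (SE 0.235), CD279 (PD-1) at 0.85 (SE 0.300), CD152 (CTLA-4) at 0.81 (SE 0.232), CD357 A (GITR) at 1.12 (SE 0.267) and CD4 B at 1.53 (SE 0.420). CD4 B varied widely, from 727 ± 226 to 3350 ± 3950 CPM (0.84 to 2.54 over the settings), and 1 library without aCD27 stood apart for it (1046 CPM, the nearest other 571) and for CD357 A (190.7 CPM, the nearest other 118). The mouse IgG1 isotype control was among the higher calls too, at 0.69 (SE 0.280), but higher in 2 of 3 donors and at 0.13 to 1.35 over the other settings. The added lower tags were CD73, an ectoenzyme that makes adenosine, at -1.72 (SE 0.359), CD117 at -1.32, CD69 at -1.23, HLA-DRA at -1.15, CD34 at -1.11, CD49b at -1.09, CD158E1 at -0.69, CD123 at -0.65 (-0.89 to -0.17 over the settings) and CD16 at -0.54 (0.0562, and so turned, with equal cell numbers). In both stimulations CD16 (31.7 CPM without aCD27 and 21.9 CPM with it) lay under all isotype controls, and CD123 (63.0 and 40.2), CD34 (128 and 63.0), CD366 (38.6 and 91.4), CD152 (90.4 and 166) and CD158E1 (151 ± 128 and 81.7 ± 35.7, 1 library without aCD27 at 429 and the nearest other at 113) under the mouse IgG1 tag. Over the settings tried, the log2 fold change of CD158E1 ranged from -1.71 to -0.22, that of CD34 from -1.64 to -0.004 (adjusted p from 6.97e-05 to 0.990, the last in cells with T cell UMIs and none of other cells), that of CD70 from 1.65 to 2.54 and that of CD73 from -1.99 to -1.57.

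At the mRNA level no gene of 11261 passed edgeR's quasi-likelihood test, with 1122 at an unadjusted p under 0.05, while DESeq2's Wald test called 77 of the same genes (51 higher and 26 lower). Without a filter, over 20004 genes, edgeR called 69 and the Wald test 78 (45 higher and 33 lower). CD27 mRNA was at 744 ± 248 CPM without aCD27 and 691 ± 327 CPM with it (log2 fold change -0.11, SE 0.345, n = 3). CD28 (-0.07, SE 0.225), CD3E (-0.09, SE 0.205) and CD8A (0.00, SE 0.206) lay near 0. MKI67, a marker of dividing cells, was at 66.5 ± 11.9 CPM and 113 ± 24.8 CPM (log2 fold change 0.76, SE 0.233, adjusted p = 0.411, higher in 3 of 3 donors). CD70 was at 0.93 (SE 0.514), CCR7, a lymph node homing receptor, at 0.23 (SE 0.194), IL2RA at 0.40 (SE 0.631), TNFRSF9 at 0.20 (SE 0.325), GZMB at 0.56 (SE 0.793) and IFNG at -0.34 (SE 0.845). The signs of CD8A, CD28, GZMB and IFNG turned under other settings.

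With the donor as a block, 13 genes passed (4 higher and 9 lower), named here after their values were seen. The higher ones were LGALS1, which encodes galectin-1 (1.64, SE 0.159), QPRT (1.83, SE 0.213), LST1 (1.38, SE 0.164) and C18orf56 (2.03, SE 0.277). LGALS1 was at 791 ± 97.2 CPM without aCD27 and 2533 ± 749 CPM with it. The lower ones held cytotoxic and NK-receptor genes whose levels without aCD27 varied widely between donors. These were GZMK (-2.31, SE 0.201, from 62.1 ± 58.7 CPM), KLRD1 (-2.41, SE 0.252, from 30.6 ± 37.5 CPM) and GNLY (-2.08, SE 0.244, from 113 ± 124 CPM). Also among the lower ones were IL7R, whose protein is CD127 (-2.33, SE 0.238), MIR155HG, the host gene of a microRNA induced by T cell activation (-2.86, SE 0.235), the interferon regulatory factor gene IRF1 (-1.63, SE 0.193), PLEK (-1.98, SE 0.222), the chemokine receptor gene CXCR6 (-2.97, SE 0.372) and SYNE2 (-1.44, SE 0.181). MIR155HG fell from 140 ± 37.4 to 20.6 ± 9.73 CPM in that fit. Without the donor block, no gene was called without donor 1 or donor 2, and MIR155HG alone without donor 3.

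Gene lists of cell division and energy metabolism lay higher with aCD27 than the other tested genes when a preset correlation was used. That test called 10 lists in all. Other splits of the 6 donor and stimulation sums gave up to 13, and 6 of the 10 splits, the real one included, gave as many. The calls below can therefore not be told from differences between donors. The fry test called 0 lists (lowest adjusted p = 0.377). The G2/M list, genes of late cell cycle and mitosis, rose by camera with a preset correlation of 0.01 (48 of 53 genes with a positive log2 fold change, median 0.35, adjusted p = 1.36e-11, but adjusted p = 0.669 with an estimated correlation). The S phase list of DNA replication genes also rose (28 of 41 positive, median 0.20, adjusted p = 0.0448, but adjusted p = 0.777 with an estimated correlation). CCNB2 (0.94, SE 0.177), AURKB (0.84, SE 0.239) and CDCA3 (0.64, SE 0.182) led the G2/M list, and CDCA7 (0.74, SE 0.182) and RRM2 (0.65, SE 0.251) were examples of the S phase list. None of these genes passed over all genes, and 1 of the G2/M genes (CCNB2) and 0 of the S phase genes passed adjusted over the list alone. Without donor 1 the S phase list had an adjusted p of 0.839, in a range of 3.70e-05 to 0.839 over its 10 alternatives.

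Glycolysis genes, which turn glucose to pyruvate and lactate, rose as a list (21 of 22 positive, median 0.48, adjusted p = 4.77e-10), as did oxidative phosphorylation (47 of 50 positive, median 0.33, adjusted p = 1.55e-10), cholesterol synthesis (20 of 21 positive, median 0.58, adjusted p = 3.45e-06) and mitochondrially encoded genes (12 of 13 positive, median 0.44, adjusted p = 1.49e-06). All 4 had an adjusted p = 0.669 with an estimated correlation. Over all genes 0 members passed, and adjusted over the list alone 5 glycolysis genes, 2 mitochondrially encoded genes and 0 of the others. SLC16A3, a lactate transporter, was at 13.6 ± 1.48 CPM without aCD27 and 50.8 ± 21.5 CPM with it (log2 fold change 1.90, SE 0.356). GAPDH (0.88, SE 0.214) and TPI1 (0.73, SE 0.179) followed, with FDPS (1.02, SE 0.289), FDFT1 (0.80, SE 0.283) and SQLE (0.59, SE 0.211) of cholesterol synthesis. COX7B (0.70, SE 0.185), NDUFB4 (0.68, SE 0.242) and COX6C (0.58, SE 0.230) led the oxidative phosphorylation list, and MT-CO3 (0.74, SE 0.188), MT-ND4 (0.67, SE 0.176) and MT-ND5 (0.69, SE 0.228) the mitochondrially encoded one. The mitochondrial share of UMIs, a sign of RNA quality, was also higher with aCD27 in 3 of 3 donors.

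Cytotoxic effector genes fell as a list (6 of 17 positive, median -0.40, adjusted p = 0.0150, but adjusted p = 0.669 with an estimated correlation), led by GZMK (-2.44, SE 0.727), SLAMF7 (-0.66, SE 0.202) and GZMH (-1.94, SE 0.632). MYC targets and ribosome biogenesis genes fell (8 of 29 positive, median -0.32, adjusted p = 0.00883, but adjusted p = 0.737 with an estimated correlation), led by ODC1 (-0.99, SE 0.293), RRS1 (-0.95, SE 0.338) and WDR43 (-0.75, SE 0.329). The list of nuclear and intronic RNA, a sign of RNA quality, fell (2 of 5 positive, median -1.01, adjusted p = 0.0186, but adjusted p = 0.669 with an estimated correlation). Its MALAT1 was at 16940 ± 7600 CPM without aCD27 and 5178 ± 1600 CPM with it, MIAT at a log2 fold change of -1.01 (SE 0.332) and KCNQ1OT1 at -1.02 (SE 0.368). Over all genes 0 members passed, and adjusted over the list alone 3 of the nuclear list and 0 of the other 2. Without donor 1 the nuclear list had an adjusted p of 0.156 (0.00251 to 0.792 over its 10 alternatives). Without donor 3 the cytotoxic list was at 0.0973 (0.000132 to 0.674) and the MYC list at 0.778 (6.05e-07 to 0.792). With equal cell numbers at one depth the MYC list did not pass either (adjusted p = 0.492).

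**Figure D2:**
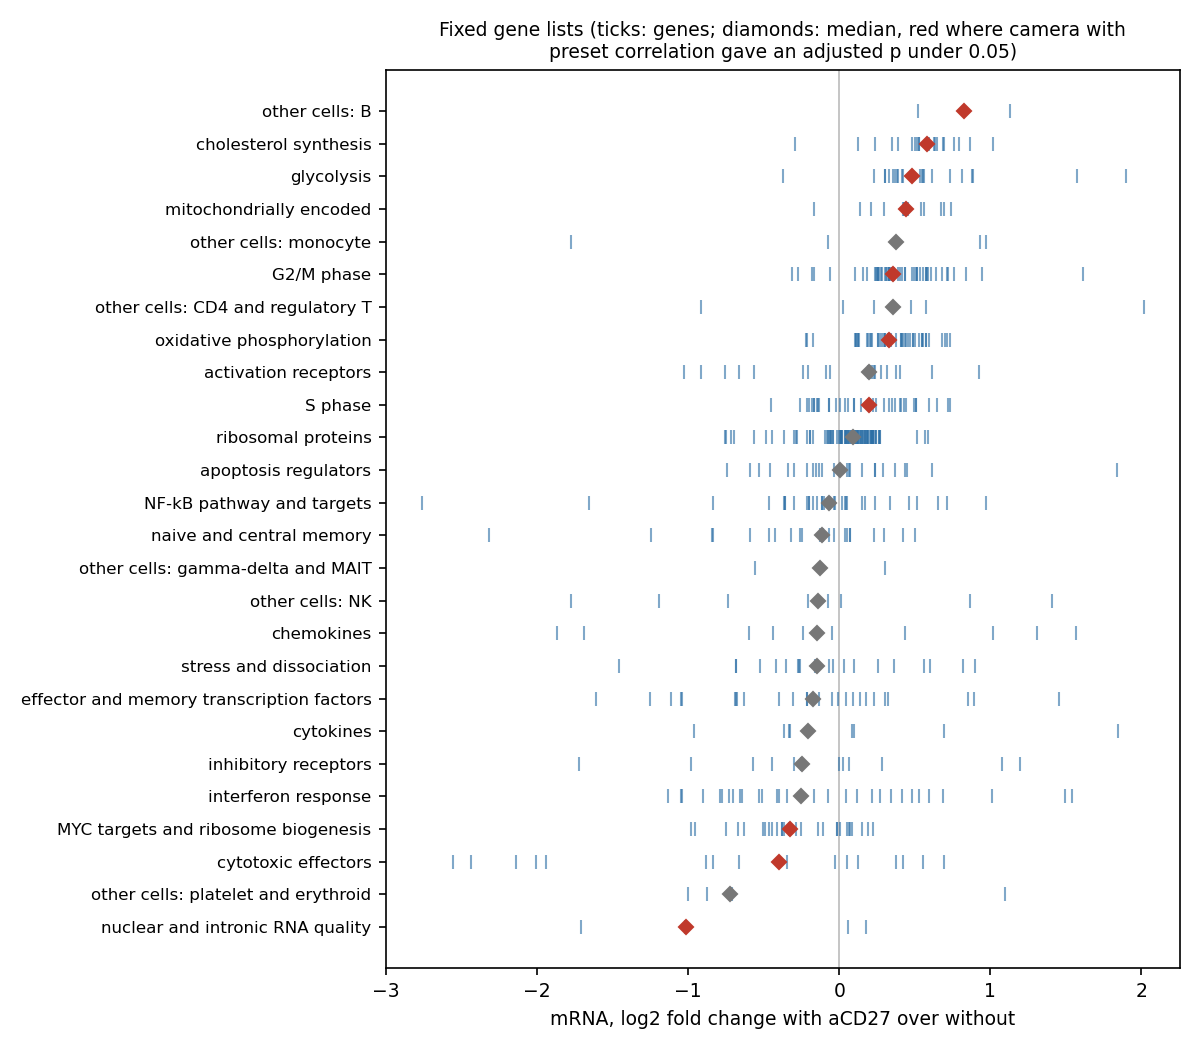
Log2 fold changes of mRNA with aCD27 over without for the tested genes of 26 fixed lists, a tick per gene and a diamond at each list's median, red for the 10 lists that camera called with a preset correlation. G2/M genes (48 of 53) and oxidative phosphorylation genes (47 of 50) lay mostly above 0, while the median of the 5 tested nuclear RNA genes was -1.01.

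Markers of other cells were tested because a naive CD8+ gate can let such cells through. The B cell list rose (2 of its 12 genes tested, both positive, adjusted p = 0.0448, and adjusted p = 0.669 with an estimated correlation), with 0 genes past the threshold over all genes and 2 adjusted over the list alone. Those were CD79A, at 65.6 ± 24.6 CPM without aCD27 and 143 ± 103 CPM with it, and CD79B (0.52, SE 0.216). Without donor 2 that list had an adjusted p of 0.0563 (0.00586 to 0.674 over its 10 alternatives), with equal cell numbers at one depth 0.0588, and in cells with T cell UMIs and none of other cells 0.189. That last setting drops cells by UMIs of other cells' genes, B cell genes among them. Its weaker value was thus built in and cannot weigh on the B cell list. MS4A1, another B cell gene, was found in 0.0352% of cells with aCD27 and 0.0939% without it at 700 UMIs (higher in 1 of 3 donors, exact permutation p = 0.4), and was lower in 3 of 3 donors without thinning (0.112% against 0.261%) and at 2 times that depth (0.0445% against 0.220%). The lambda light chain tag fell. Markers of monocytes (3 of 5 positive, adjusted p = 0.491, AIF1 0.97 and TYROBP -1.78), NK cells (3 of 8, adjusted p = 0.805, SPON2 1.41 and MYOM2 0.87) and CD4 and regulatory T cells (5 of 6, adjusted p = 0.449, FOXP3 2.02 and ZBTB7B 0.58) did not pass. Those of gamma-delta and MAIT cells (1 of 2, adjusted p = 0.491, KLRB1 -0.56 and ZBTB16 0.30) and platelets with erythroid cells (1 of 5, adjusted p = 0.0688, HBB 1.10 and HBA1 -0.88) did not pass either. Adjusted over the list alone, AIF1 passed and 0 genes of the last 4 lists, against 0 over all genes. With the donor as a block the platelet and erythroid list fell (adjusted p = 0.0218, but adjusted p = 0.792 with an estimated correlation and the block, in a range of 0.000161 to 0.959 over its 10 alternatives).

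The naive and central memory list did not pass (8 of 22 positive, median -0.12, adjusted p = 0.0559) and fell with the donor as a block (adjusted p = 0.0190, but adjusted p = 0.792 with an estimated correlation and the block, 0.000161 to 0.792 over its 10 alternatives), led by IL7R and the lymphotoxin gene LTB (-0.84, SE 0.295). No call was made for activation receptors (11 of 20 positive, mean -0.03, median 0.20, HLA-DRA -1.03, but 0.20 in cells with T cell UMIs and none of other cells, and HLA-DRB1 -0.76) or inhibitory receptors (5 of 13, HAVCR2 1.08 and CD160 -1.72). Nor was one made for the NF-kB pathway (13 of 33, MIR155HG -2.76 and IRF1 -1.66), chemokines (4 of 10, median -0.14 with camera upward, CCL22 1.57 and CCL5 -1.69), cytokines (4 of 9, mean 0.06, median -0.21, TGFB1 1.85, higher in 2 of 3 donors and at -0.0672 without 1 of them, and TNFSF14 -0.96) or effector and memory transcription factors (10 of 26, MYC -1.05 and ID3 0.85). Interferon response genes (13 of 30, GBP5 -1.14), apoptosis regulators (12 of 24, median 0.01 with camera downward, BBC3 1.84 and BID -0.74), stress and dissociation genes (8 of 21, DDIT4 0.90 and ZFP36 -1.46) and ribosomal proteins (63 of 88, RPL34 -0.76) were not called. Their adjusted p values lay at 0.185 or above. Leaving out 1 donor made calls in 6 lists of this and the last paragraph. Without donor 1 the NF-kB list fell (0.0146, over all its alternatives 0.0146 to 0.792), interferon response fell (0.0317, 0.000143 to 0.879) and ribosomal proteins rose (0.0146, 0.0146 to 0.866). Without donor 2 the transcription factors fell (0.0430, 0.0430 to 0.801), as did interferon response (0.0286), and without donor 3 the naive and central memory list and the platelet and erythroid list did (0.000161 each). Adjusted over the list alone, 2 NF-kB genes (MIR155HG and IRF1), 1 chemokine (CCL22), 1 naive and central memory gene (IL7R), 3 transcription factors and 3 interferon response genes passed, and 0 of the other lists of this paragraph, against 0 over all genes.

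Protein and mRNA responses were then set side by side for 39 pairs of an antibody and its single gene (37 genes). Across pairs, which are not independent replicates, Pearson's r of the log2 fold changes was 0.582 (permutation p = 0.00019) and Spearman's rho 0.616 (permutation p = 8e-05), with a Benjamini-Hochberg adjusted p of 0.00019 for the larger of the 2. The sign was the same in 31 of 39 pairs. IL7R and its CD127 tag (-2.32 and -2.36), NT5E and CD73 (-1.77 and -1.66), and HLA-DRA mRNA and tag (-1.03 and -1.10) lay close together, though in cells with T cell UMIs and none of other cells HLA-DRA was at 0.20 and -0.56. The CD127 tag ended under the mouse IgG1 tag with aCD27 (74.0 and 281 CPM). CD27 was at -0.11 as mRNA and -3.66 as tag, and CD34 at 0.37 and -1.03 (tag at -0.004 in cells with T cell UMIs and none of other cells). FOXP3, a nuclear factor, was at 2.02 and -0.01. Its mRNA was scarce, at 0.401 ± 0.365 CPM without aCD27 and 1.93 ± 0.812 CPM with it. Without the 2 pairs farthest on the mRNA axis (IL7R and NT5E, with their tags), r was 0.431 (permutation p = 0.0115). Among 18 pairs whose gene had at least 50 CPM, r was 0.479 (permutation p = 0.0614) and 17 of 18 signs were the same.

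Shares of cells with a UMI were compared after thinning to 700 UMIs, which left out 19 cells of 1 donor without aCD27 and 0 cells of the other sums. Cells with a UMI of MKI67 made up 6.10% ± 0.830 with aCD27 and 2.41% ± 0.880 without it (SD, n = 3), higher in 3 of 3 donors (exact permutation p = 0.1, the smallest possible). Shares with and without aCD27 were 22.1% ± 2.62 and 18.6% ± 3.63 for CCR7, 8.24% ± 6.46 and 5.89% ± 4.62 for IL2RA, and 14.3% ± 6.05 and 10.3% ± 2.78 for TNFRSF9, higher in 3, 2 and 2 of 3 donors, with exact permutation p values of 0.3, 0.8 and 0.4. They were 3.91% ± 3.63 and 3.03% ± 2.10 for GZMB, 0.396% ± 0.341 and 0.580% ± 0.550 for IFNG, and 12.9% ± 2.44 and 13.1% ± 0.279 for CD8A, higher in 1, 2 and 1 of 3 donors, with exact permutation p values of 0.9, 0.8 and 0.9. As background, genes that naive CD8+ T cells should lack gave 0.0805% and 0% (CD4), 0.0352% and 0.0939% (MS4A1) and 0.112% and 0.138% (LYZ). Without thinning the MKI67 shares were 41.2% and 15.4%, those of CD4 0.612% and 0.0298%.

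In PBMC, the first comparison asked how enrichment changed the cell types captured. T-like cells made up 77.9% (95% exact interval 76.6 to 79.2) of the CD3-enriched library and 34.1% (32.7 to 35.5) of unsorted PBMC treated alike. Monocyte-like cells made up 91.2% (90.1 to 92.2) of the CD11b-enriched library and 35.0% (33.5 to 36.4) of unsorted PBMC treated alike. B-like cells were 2.51% (2.03 to 3.06) and 0.495% (0.271 to 0.829) of the enriched libraries, and 12.2% (11.2 to 13.2) of the unsorted library. NK-like cells, whose cluster also held CD3D at 10.7 per 10000 UMIs and so cytotoxic T cells, were 17.1% of CD3-enriched, 2.47% of CD11b-enriched and 12.7% of unsorted cells. No plasmacytoid dendritic-like cell was seen among 3789 CD3-enriched or 2830 CD11b-enriched cells, which allows shares of up to 0.0973% and 0.130% by the exact interval. There was 1 library per condition and so no replicate check.

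**Figure D3:**
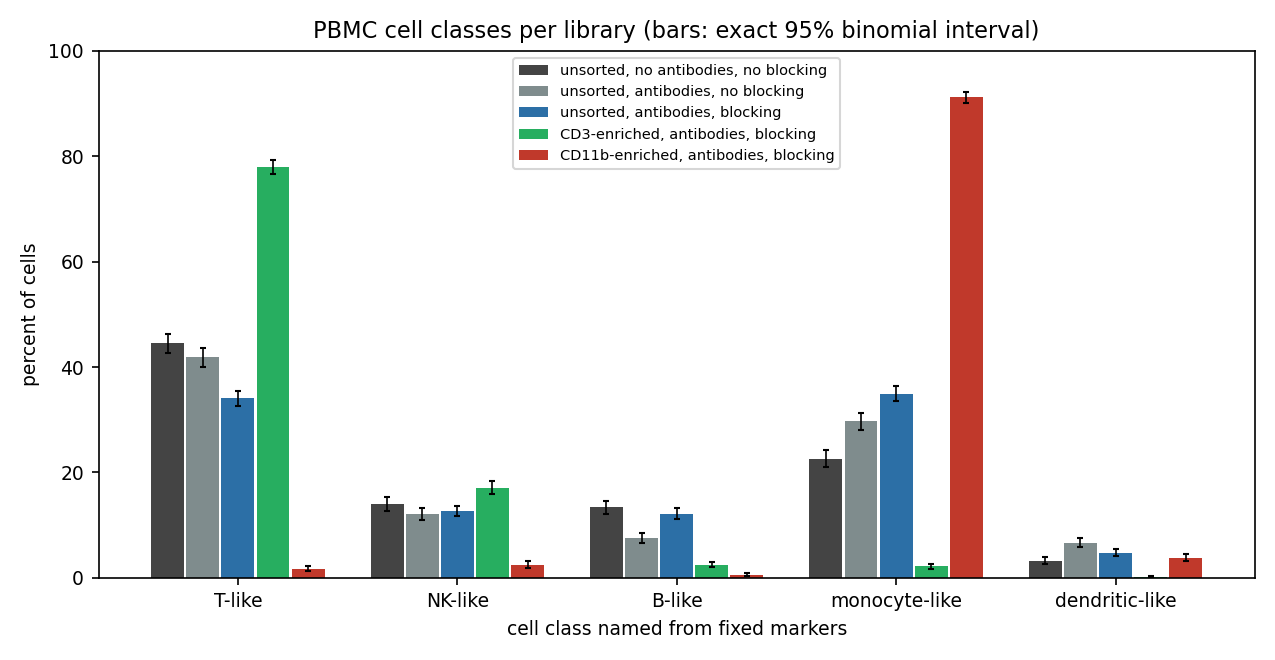
Percent of cells in 5 cell classes for the 5 PBMC mRNA libraries, with black bars for the exact 95% binomial interval, which covers counting error only. T-like cells reached 77.9% in the CD3-enriched library and monocyte-like cells 91.2% in the CD11b-enriched library.

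Labelling with antibodies and blocking were compared for their mRNA profiles in unsorted PBMC, 1 library each. Between the library with antibodies and the one without, Pearson's r across genes was 0.990 and 12 of 1963 genes at 50 CPM or more differed over 2-fold (3 higher and 9 lower). CD14, a monocyte receptor gene, was at 404 and 194 CPM (ratio 2.08, 1.93 to 2.25), RAB24 at 75.5 and 35.5 CPM and IGLL5 at 1268 and 617 CPM. IFITM1 (ratio 0.266, 0.218 to 0.322), C1QBP (0.346), C17orf89 (0.365), FAM26F (0.394), the platelet gene PPBP (0.406), KRT10 (0.454), RP1-241P17.4 (0.462) and ARF6 (0.469) were lower with antibodies. With antibodies and blocking against neither, r was 0.984 and 233 of 2260 genes differed (167 higher and 66 lower), the highest being TBC1D22A (3.55), FCGR2A (3.25), CSTA (3.09), PES1 (3.03), CD14 (2.98), SULT1A1 (2.85), CD151 (2.83) and PRR14 (2.80). The lowest were C17orf89 (0.321), FAM26F (0.324), SVIP (0.328), EIF3E (0.343), IFITM1 (0.350), KRT10 (0.352), TMEM256 (0.369) and IGJ (0.385). Between blocking and no blocking, both with antibodies, r was 0.990 and 13 of 2224 genes differed, all higher with blocking, MT-ND6 (3.35), CLU (3.21), TBC1D22A (2.80), PES1 (2.69), TMX2 (2.67), FCRLA (2.45), PRR14 (2.34) and BTK (2.22) in front. Monocyte-like cells were 22.6%, 29.7% and 35.0% of these libraries without antibodies, with antibodies, and with antibodies and blocking. Weighting 7 cell classes equally gave 97, 407 and 233 genes over 2-fold, and for CSTA a ratio of 1.21. Those classes included plasmacytoid dendritic-like cells (19, 33 and 25 cells) and platelet-like cells (47, 37 and 35 cells). Equal weights raise the counting noise of such small classes, so the higher numbers of genes cannot be read as a correction for cell composition.

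Blocking buffer went with fewer antibody tags per cell in most cell classes. All cells together held a mean of 535.9 tags without blocking (SD 1316 between cells) and 290.1 with it, a ratio of 0.541 (0.540 to 0.543). The medians were 196 and 166 (ratio 0.847), 356.5 and 226.5 in B-like cells (0.635), and 208 and 243 in NK-like cells, which turns their direction. The ratio of means was 0.389 in B-like cells, 0.405 in monocyte-like cells, 0.453 in dendritic-like cells and 0.408 in platelet-like cells, but 0.640 in T-like cells and 0.954 in NK-like cells, with 1.23 in the 33 and 25 plasmacytoid dendritic-like cells. Isotype control tags per monocyte-like cell were 5.19 and 1.17 (ratio 0.226) and per T-like cell 0.666 and 0.457 (ratio 0.686). All 46 tags compared were lower per cell with blocking, 19 of them over 2-fold, but as shares of all tags of the library 24 were lower and 22 higher, HLA-DRA (ratio 1.39), CD20 (1.34) and CD3 (1.31) in front. CD68, a mostly intracellular macrophage protein, had a ratio of 0.0677 (0.0627 to 0.0731), followed by mouse IgG1 (0.261), CD45 A (0.269), CD197 (0.289), CD25 (0.297), CD274 (0.341), CD335 (0.398) and CD9 (0.408). Monocyte-like cells without blocking held a mean of 7.42 CD68 tags but a median of 0, so cells with many tags weighed on that ratio. Means without and with blocking were 0.308 and 0.0923 in T-like cells, and 0.801 and 0.198 in dendritic-like cells. The interval does not cover the spread between cells. Depth moved with blocking as well, with 1.69 M tags over 3158 cells without it and 1.26 M over 4330 cells with it. As the mean share of each cell's tags, 1 tag (CD68, ratio 0.340) was over 2-fold lower, and as shares of all tags of the library 3 were (CD68 0.125, mouse IgG1 0.482 and CD45 A 0.498). Within the 5th to 95th percentile of tag totals the ratios were 0.926 (T-like), 0.852 (NK-like), 0.597 (B-like), 0.477 (monocyte-like), 0.449 (dendritic-like) and 0.366 (platelet-like).

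**Figure D4:**
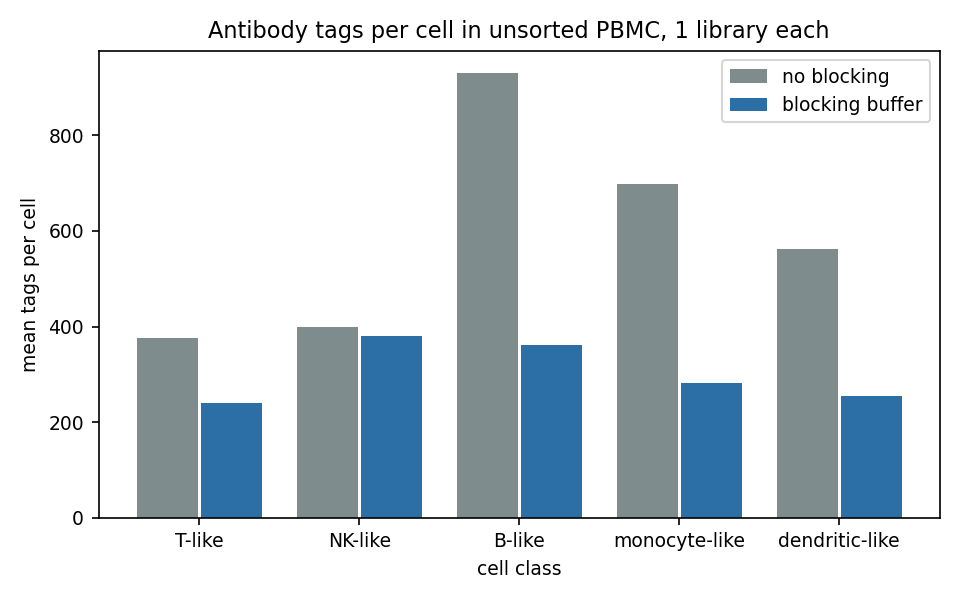
Mean antibody tags per cell in 5 cell classes of unsorted PBMC, 1 library without blocking buffer (grey) and 1 with it (blue), so bars carry no replicate error. B-like cells held 930 and 362 tags and NK-like cells 398.1 and 380.0.

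Protein and mRNA of the same PBMC were compared pair by pair, over the 3155 and 4259 cells of the unsorted libraries without and with blocking. With blocking, Spearman's rho across cells between the tag share and the mRNA was highest for HLA-DRA (0.756), CD14 (0.558), CD20 and its gene MS4A1 (0.457), CD27 (0.399), CD8 B and CD8A (0.382), CD3 and CD3E (0.362), CD8a (0.355) and CD8 A (0.352). It was 0.132 for CD11b, and 0.0851 and 0.0972 for CD4 A and CD4 B. The 4 lowest values were those of CD69 (-0.0298), CD223, CD45RO (-0.0182, gene detected in 18.5% of cells) and CD152. The median rho over 41 pairs, some of whose genes were found in under 0.5% of cells, was 0.0747, and 0.0679, 0.0874 and 0.0503 in the unsorted library without blocking and the CD3-enriched and CD11b-enriched libraries. Within a cell class several of these were lower. Within T-like cells of the library with blocking, HLA-DRA was at 0.0570, CD27 at 0.0604 and CD3 at 0.0362 (0.0234 over the CD3-enriched library), and within monocyte-like cells CD14 was at 0.159 and HLA-DRA at 0.327. CD8 B, CD8a and CD8 A were at 0.449, 0.402 and 0.391 within T-like cells. Within T-like and monocyte-like cells of the 4 libraries the medians were 0.0271 to 0.0739. At 500 UMIs per cell, CD3E was detected in 41.1% (38.6 to 43.7) of T-like cells (60.4% without thinning), and MS4A1 in 40.2% (35.9 to 44.6) of B-like and 0.281% (0.0767 to 0.719) of T-like cells. Median depths were 996 UMIs for T-like and 1152 UMIs for B-like cells. CD4 mRNA was detected in 3.02% of T-like cells and 5.79% of monocyte-like cells, against 0 of 500 B-like cells (0.772% without thinning).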

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

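All comparisons in this part were planned. Among 98 groups of 4 to 10 libraries, 8 held a library whose gap to the nearest other was a large part of the group's range (Dixon's 95% limit), and chance gives about 5% of groups. Of the 4 libraries with aCD3+aCD28, 1 had a median mitochondrial share of 4.72%, the nearest other 3.26%. IL2 mRNA, the gene of the T cell growth factor interleukin-2, was at 0.759 CPM in 1 of these 4 libraries (a single UMI) and at 0 in the other 3. Of the 6 libraries with aCD27, 1 had IL2 at 1.65 CPM (32 UMIs) and the nearest other 0.304 CPM (4 UMIs).

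Tags stood apart in 1 of the 4 aCD3+aCD28 libraries each. CD73, an ectoenzyme, was at 2225 CPM (nearest other 1031), and CD357 A (GITR) at 190.7 CPM (nearest other 118.3). CD4 B was at 1046 CPM (nearest other 571.1), CD123 (interleukin-3 receptor alpha chain) at 79.4 CPM (nearest other 55.4), and CD158E1, a killer cell immunoglobulin-like receptor, at 429.3 CPM (nearest other 112.6). The Blank entry, which names no antibody, held 8 counts in the unsorted PBMC library with blocking, 13 in the CD11b-enriched library and 5 in 1 CD8+ T cell library with aCD27, above the 3 counts that a count of 0 allows. The libraries with aCD3+aCD28 came from 3 donors, so a library that stood apart can be a donor that stood apart. That does not hold for the mitochondrial share, since the library at 4.72% and the nearest other at 3.26% both came from donor 1. CD73 was highest in donor 3 without and with aCD27 (2213 and 761.1 CPM). CD4 B (986.1 and 7909 CPM) and CD357 A (179.7 and 453.8 CPM) were highest in donor 2. No explanation was tested for the values of this part.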

How the results depend on the processing

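Alternatives added after the data were seen were equal cell numbers at one depth, DESeq2's Wald test on the filtered genes, lists on cells with T cell UMIs and none of other cells, fry and estimated correlation with the donor block, the responses without the 2 farthest pairs, and tags with blocking as medians per cell and as shares of all tags of the library. Of 1221 alternative values of 82 genes, 1107 kept their direction and side of the threshold, 89 passed it newly and 25 changed sign. Of 416 values for 32 tags the numbers were 321, 77 and 9, with 9 no longer past the threshold. Of 259 values for 26 gene lists, 182 were the same, 13 passed newly, 48 no longer passed and 16 changed direction. All 20 alternative values of cell yield and depth were the same. The cause was not tested for any change below unless one is named.

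Against 0 genes by edgeR without a block (1122 at an unadjusted p under 0.05), 13 genes passed with the donor as a block, 77 by DESeq2's Wald test, 78 by that test without a filter on low counts (20004 genes, 2 choices changed at once), 69 by edgeR without a filter, 1 with equal cell numbers and 2 among genes at 50 CPM or more. With equal cell numbers at one depth 30 passed, among 3476 genes tested. Leaving out 1 donor gave 0 to 1, the 1 (MIR155HG) without donor 3. Against 6 tags, 25 passed with the block, 14 with total counts (5 of the 6), 26 by the Wald test, 10 with 1 library per donor and stimulation, 13 with equal cell numbers (4 of the 6), 11 with T cell UMIs and none of other cells, and 17 by limma on centred log ratios. Leaving out 1 donor gave 2 to 14 tags, 2 without donor 2, 14 without donor 3 and 5 (4 of the 6) without donor 1. The 6 tags kept their direction in all settings. Against 10 lists, 0 passed with an estimated correlation, 0 by fry, and 0 by each of these with the donor block. Leaving out 1 donor gave 10 to 11 lists. With equal cell numbers at one depth 12 of 25 lists passed, 8 of the 10 among them. The MYC list (0.492, 6.05e-07 to 0.792 over its alternatives) and the B cell list (0.0588, 0.00586 to 0.674) did not. Newly called there were the naive and central memory list (0.0150, 0.000161 to 0.792), interferon response (0.000143, 0.000143 to 0.879) and ribosomal proteins (0.0196, 0.0146 to 0.866), all lower, and the 1 gene left of the monocyte list (0.0184, 0.0184 to 0.895), higher. In cells with T cell UMIs and none of other cells 10 lists passed, 9 of them the same. With the donor block 12 lists passed, the naive and central memory list and the platelet and erythroid list beside the 10, and the block ended no call of a gene, tag or list.

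Lists that changed direction had these adjusted p values. With the donor block, apoptosis regulators had 0.916 (0.929 with an estimated correlation too; 0.530 to 0.991 over all alternatives). With equal cell numbers at one depth, stress genes had 0.937 (0.185 to 0.937), platelet and erythroid markers 0.959 (0.000161 to 0.959) and ribosomal proteins 0.0196. In cells with T cell UMIs and none of other cells, activation receptors had 0.262 (0.0522 to 0.929), NK markers 0.583 (0.202 to 0.892) and platelet and erythroid markers 0.202. Without 1 donor, the ranges of lists that changed direction were 0.787 to 0.991 (apoptosis), 0.202 to 0.538 (NK), 0.541 to 0.787 (chemokines), 0.0731 to 0.895 (monocyte), 0.540 to 0.787 (activation receptors), 0.675 to 0.879 (cytokines), 0.0286 to 0.879 (interferon response) and 0.0146 to 0.523 (ribosomal proteins).

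Log2 fold changes that changed sign were mostly near 0. CD8A mRNA was at -0.0235 with the donor block, -0.0116 with DESeq2 size factors, -0.0723 with total counts, -0.0118 by the Wald test (-0.000375 without a filter), -0.0659 with 1 library per donor and stimulation, -0.00788 with all deposited cells, -0.0354 with equal cell numbers, -0.00688 with T cell UMIs and none of other cells, -0.0405 among genes at 50 CPM or more and -0.29 at one depth. CD28 was at 0.11 at one depth, IFNG at 0.83 with equal cell numbers, and HLA-DRA at 0.20 with T cell UMIs and none of other cells. GZMB was at -0.0704 with the donor block and -0.31 at one depth, and HBA1 at 0.0125 with equal cell numbers. Without 1 donor, ranges were -0.31 to 0.10 (CD28), -0.20 to 0.16 (CD8A), -1.08 to 0.11 (IFNG), -0.71 to 1.06 (GZMB), -0.0672 to 2.62 (TGFB1), -2.26 to 0.0449 (TYROBP), -2.38 to 0.0647 (KLRB1) and -0.17 to 1.46 (HBB). The CD8a tag was at -0.0409 with 1 library per donor and stimulation, -0.13 with all deposited cells and -0.14 with T cell UMIs and none of other cells, CD25 B at 0.0079 with 1 library and 0.0261 with equal cell numbers, and CD16 at 0.0562 with equal cell numbers. Without 1 donor the CD8 A tag ranged from -0.52 to 0.0158 and the CD8a tag from -0.28 to 0.33.

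Depth limits the shares of cells with a UMI. The difference with aCD27 was 3.69 points for MKI67 at 700 UMIs, 7.11 at 2 times that depth and 25.8 without thinning. It was 4.83 and 19.5 for IL2RA (2.35 at 700 UMIs), and 21.3 without thinning for TNFRSF9. Pearson's r between mRNA and tag responses was 0.479 among genes at 50 CPM or more, where fewer pairs (18) were left.

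In PBMC, T-like cells in the CD3-enriched library made up 74.7% at Leiden resolution 0.4, 66.1% at 1.6, 89.3% with 10 principal components, 74.3% with 40, 72.4% with all deposited cells and 74.7% without scrublet's doublets. Monocyte-like cells in the CD11b-enriched library made up 95.3%, 87.4%, 94.2%, 95.02%, 95.2% and 94.8% in that order. In unsorted PBMC with blocking, T-like cells were 28.6% at resolution 1.6 and 41.0% with 10 principal components, and monocyte-like cells 39.8% at resolution 0.4, 39.5% with 10 and 39.7% with 40 principal components, 39.9% with all deposited cells and 39.4% without scrublet's doublets. Both enriched classes stayed above their unsorted shares in all of these. For labelling, labelling with blocking, and blocking alone, r was 0.992, 0.982 and 0.990 with a pseudocount of 10 and 0.976, 0.968 and 0.973 with equal class weights. Genes over 2-fold were 2, 68 and 0 at 200 CPM or more, where fewer genes were compared. With equal class weights, which raise the counting noise of small classes, they were 97, 407 and 233. Within the 5th to 95th percentile of tag totals, ratios with blocking were 0.657 (all cells), 0.597 (B-like), 0.852 (NK-like), 0.926 (T-like), 0.477 (monocyte-like), 0.366 (platelet-like) and 0.998 (plasmacytoid dendritic-like, 1.23 over all such cells). As ratios of medians per cell they were 0.847, 0.635, 1.17, 0.852, 0.575, 0.347 and 1.02 in that order (dendritic-like 0.554), so that NK-like cells changed direction. Against 19 tags over 2-fold different per cell, 1 was as the mean share of each cell's tags and 3 were as shares of all tags of the library.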

Other observations

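Tests chosen after the result was seen were the 3 on the lower CD27 tag and 2 on the higher CD4 tags (CD4 made by stimulated CD8+ T cells, and the same rise of all tags). In unsorted PBMC with blocking, several lineage tags lay highest on the matching cell class, while CD8 A and CD8a averaged 153 and 137 per NK-like cell against 78.7 and 68.2 per T-like cell (CD8A mRNA was at 2.42 per 10000 UMIs in the NK-like cluster, which also held CD3D, against 0.664 and 0.750 in the T-like clusters). CD20, a B cell protein, averaged 73.0 tags per B-like cell and 1.19 per T-like cell. CD14 and CD33, myeloid proteins, averaged 19.8 and 64.2 per monocyte-like cell, and CD158E1 and CD56 14.7 and 1.16 per NK-like cell. CD4 B averaged 21.5 per T-like and 8.46 per monocyte-like cell, CD3 4.06 per T-like and 1.24 per B-like cell, and HLA-DRA 40.7 per B-like and 1.26 per T-like cell. In the CD8+ T cell cultures, 89.5% to 96.0% of cells had a T cell UMI without aCD27 and 93.8% to 98.8% with it, at different depths. Cells with a UMI of MS4A1, CD79A, LYZ, CD14, FOXP3 or CD4 made up 10.9% to 23.5% without aCD27 and 39.1% to 52.7% with it, also at different depths. With aCD27 and without thinning, MS4A1, LYZ and CD4 were found in a mean of 0.112%, 0.565% and 0.612% of cells. CD79A mRNA was at 143 CPM there and FOXP3 mRNA at 1.93 CPM. MS4A1, LYZ and CD4 thus made up little of the pooled share, which is not a share of cells of other types.

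The 6 donor and stimulation sums can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes and the highest other 0, so that all 10 splits gave as many. It gave 6 tags, with a highest other of 0, so that 1 split (the real one) gave as many. It gave 10 lists, with a highest other of 13, so that 6 splits gave as many, and among splits that also part 3 donors the highest was 13 as well. Other splits that part the donors swap the stimulations of 1 donor.

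The CD27 tag was 12.6-fold lower with aCD27, while its mRNA was at 744 and 691 CPM. Scaling of tags to each other is argued against, since CD27 tags per cell fell by at least 2.94 on the log2 scale in each donor. Lower mRNA is argued against as well, since its fall reached at most 0.101 of that of the tag. It may be that the stimulating antibody took the binding site of the barcoded one, which stays open: with aCD27 the tag lay 3.90, 7.26 and 7.57 times above the highest isotype control tag, neither near it nor over 10 times above. Loss of CD27 from the surface through stimulation was not tested and stays open too.

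CD4 A and CD4 B tags together rose from 1.19, 2.11 and 0.718 per cell to 3.35, 17.2 and 2.71 in the 3 donors (medians 0, 0 and 0 to 1, 10 and 1; the top 5% of cells held 46.0% to 69.0% of these tags without aCD27 and 24.9% to 40.8% with it). CD4 T cells carried through the gate are argued against, since cells with a UMI of CD8A or CD8B and none of CD4 showed at least 0.835 of the rise (log2 over log2). In each donor the upper quartile of the log2 rises per cell of the other tags reached at most 0.682 of that of the CD4 tags. As large a rise as that of the CD4 tags was seen in 5 of 79, 1 of 77 and 1 of 76 other tags. The CD4 tags had been taken up for their rise relative to the other tags. This comparison therefore cannot decide whether all tags rose alike. More antibody of every kind bound per cell stays open as well. CD4 tags over isotype control tags rose 5.14 and 1.87 times in 2 donors but 1.15 times in 1. CD4 made by stimulated CD8+ T cells may contribute and stays open, since CD4 had at most 1 UMI per donor without aCD27 and 19 to 39 with it, and the lowest 95% bound of its ratio was 0.341.

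Monocyte-like cells held a median of 43 CD8 tags without blocking and 21 with it. Free antibody in every droplet is argued against, since these medians were at least 1.91 times those of B-like cells. Doublets with CD8 T cells stay open. Monocyte-like cells with no T cell UMI held 0.907 and 0.952 of the median of all monocyte-like cells. They were 781 of 937 and 1378 of 1489 of those cells, so their median could hardly differ and cannot decide this. Antibody bound through Fc receptors may be the source and stays open: the ratio of mean tags without over with blocking was 2.10 times that of T-like cells (1.46 by medians) but 0.905 of that of B-like cells (1.07 by medians), which carry Fc receptors too. The 2 libraries were single and no biological explanation was tested.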
